A study of Mus musculus with 24 samples.

How the data were processed

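Inguinal white adipose tissue, a subcutaneous fat depot, was taken from male C57BL6 mice after 1 hour of exercise or after a sham hour on an artificial treadmill, per the series' design text and the labels. The times are ZT3, early in the rest phase, and ZT15, early in the active phase, where ZT counts hours from lights on. The design text lists sampling at several hours after the bout and other tissues. The labels of these 24 libraries call the animals sampled at ZT3 or sampled at ZT15, so by the labels ZT is the time of sampling. They give no hour after the bout, so that hour is not stated here. Exercise at ZT3 or at ZT15 names these labelled groups below. The 4 groups of 6 libraries are called SED (sham) and RUN (exercised) at each time, and a library is named by time, group and replicate number, as in ZT3_SED_1. Replicate numbers were given in the order of the records and pair no samples. The labels do not say in words that each library is a separate mouse, although the design text gives 6 per group, so p-values measure the spread between these libraries.

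Libraries were made from total RNA with a stranded kit after removal of ribosomal RNA, per the labels' protocols. STAR, Subread 1.6.2, featureCounts and limma 3.48.3 are named, without role or order, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. No coordinates are printed, and genes are named by the symbol and Ensembl identifier that the table pairs, all 16233 of which were found in the GENCODE M21 name table. Reads of overlapping, antisense or near-identical genes cannot be told apart without the counting settings.

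The deposited table holds 16233 genes and 1 column of normalized signal per library, made by the authors before deposit. In each column every value was a whole multiple of 1 step: 100% of values came out as whole reads within a tolerance of 0.01 of a read. The factors behind these steps equalled edgeR's TMM factors recomputed on the recovered reads to within 8.882e-16, so the deposited signal is reads scaled to a common library size with TMM. The unit was thus normalized and not raw counts, and the test planned for normalized values was used. Recovered reads per library ranged from 18.5 to 34.7 M (mega) reads in the listed genes. The table's filter on low genes was made by the authors and is not described in the sources used here. Among 60 pairs of libraries within a group, the lowest chi-square per degree of freedom over genes was 23.3, so no library was a duplicate of another of its group within sampling noise. Pairs across groups were not compared in this way.

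Values were analysed as log2(value + 1), which understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in a single group-means model over all 24 libraries, with Benjamini-Hochberg adjustment over 16233 genes and a threshold of 0.05. All adjusted p-values of single genes are from this limma test unless another tool is named. Contrasts were exercise at ZT3, exercise at ZT15, their difference (the interaction), ZT15 against ZT3 in sedentary mice, and exercise averaged over both times. Gene lists, 25 in all, were fixed before the data were examined and tested in the first 4 contrasts with limma's camera at a preset correlation of 0.01, adjusted over the 100 tests, with camera at an estimated correlation and fry as alternatives. With an estimated correlation 0 of the 100 list tests passed. Scores of cell type lists (mean z score per library) were compared by exact two-sided permutation tests over the 924 splits of 12 libraries, adjusted over 33 tests.

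The rule for named genes was fixed at the same time. It took, per contrast, up to 8 higher and 8 lower genes of largest change among those past the threshold with a named symbol and expression above the median, or the 5 of smallest p where none passed. It added from each gene list up to 4 members past the threshold, or the 2 most abundant members, and a fixed set of clock, exercise and adipose genes. Any other gene named was chosen after its values were seen, which is said beside it.

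Each result was recomputed with quantile normalization, centring on the library median, leaving out the lowest 25% of expression, a pseudocount of 0.1, no trend, robust moderation, only the groups compared, the blocks of title numbers in the model, sample weights, lymphocyte and muscle scores as covariates, a threshold of 0.1 or an added log2 fold of 1, and leaving out each library. Title numbers run from 1 to 24, and each run of 8 (1 to 8, 9 to 16, 17 to 24) holds 2 libraries of every group. The labels do not say what the numbers mean. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, covariates together with these blocks, neighbouring title numbers as a replicate block, and leaving out the 3 libraries with a Cd79a value above 5.

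The pipeline was tested on simulated reads of 16233 genes with changes put in at ZT15. It recovered 23.9% of 67 genes changed 1.5-fold, 76.1% of 67 genes changed 2-fold and 89.4% of 66 genes changed 4-fold. Of 133 calls 7 were unchanged genes (5.26%), and 0 genes were called at ZT3, where none was changed. The list test called the 1 list that was shifted and 0 of the others. Simulated genes were drawn independently of one another. This run therefore cannot tell how often lists are called wrongly where genes vary together.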

Results

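Gene expression was measured by RNA sequencing of inguinal white adipose tissue in 24 libraries, 6 from each combination of time (ZT3, early rest phase, or ZT15, early active phase) and treatment (SED, sham, or RUN, 1 hour of exercise). Mean depth in the listed genes, in M (mega) reads, was 29.4 ± 3.77 M in ZT3 SED, 29.0 ± 4.58 M in ZT3 RUN, 28.2 ± 3.18 M in ZT15 SED and 27.6 ± 4.70 M in ZT15 RUN (SD, n = 6 each). Scd1, a fatty acid desaturase, took the most reads in every library. Changes are log2 differences ± SE, and group levels are deposited values as mean ± SD with n = 6.

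The libraries held different amounts of neighbouring tissues. Cd79a, a B cell receptor component, was at 99.2 in ZT3_RUN_4, 54.6 in ZT15_SED_5 and 14.1 in ZT15_SED_3, against at most 1.33 in each other library. The inguinal depot contains a lymph node. Myh4, a fast myosin of skeletal muscle, ranged from 0.631 in ZT15_SED_5 to 22113 in ZT15_RUN_6. Of the 33 exact permutation tests of cell type scores between groups 0 passed the adjustment, and 1 had an unadjusted exact p under 0.05: Schwann cell and nerve markers were higher by 1.03 in z score in ZT15 RUN than in ZT15 SED (exact permutation p = 0.0216, adjusted 0.667). The lymphocyte score was lower in ZT15 RUN than in ZT15 SED by a difference of -0.92 (exact permutation p = 0.0541, adjusted 0.667).

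**Figure D1:**
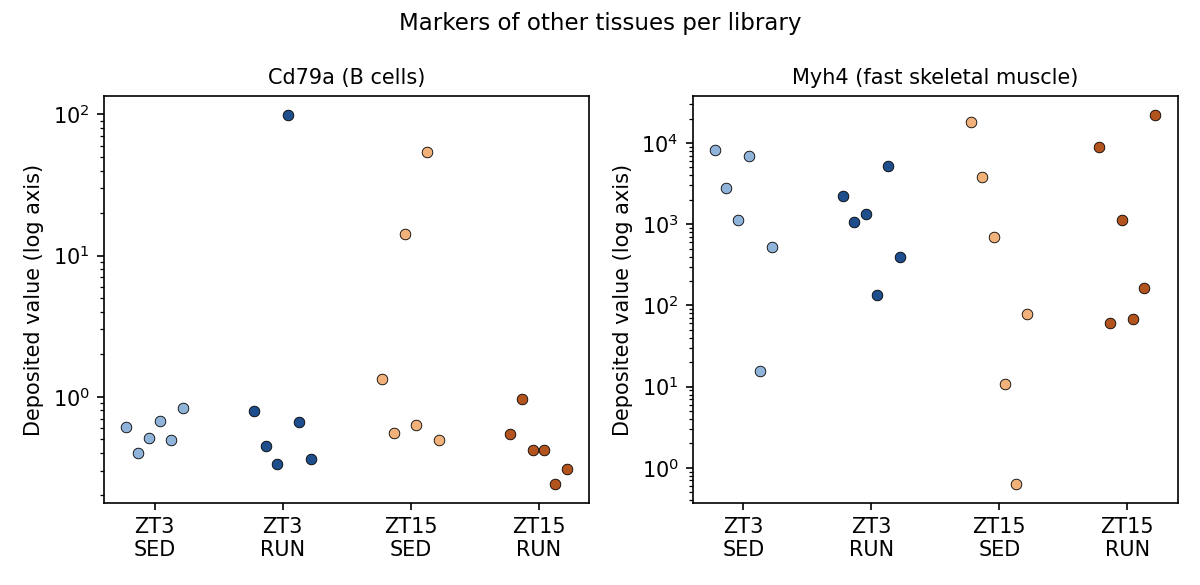
Deposited values of Cd79a (B cells) and Myh4 (skeletal muscle) per library on log axes, 6 points per group. Cd79a stood out in 3 libraries, at 99.2, 54.6 and 14.1, and Myh4 spread from 0.631 to 22113.

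The first question was which genes differed after exercise at ZT15. Exercise at ZT15 raised several transcription factors and signalling genes. Irf4 (ENSMUSG00000021356), a transcription factor of the interferon regulatory family, rose by 3.28 ± 0.68, from 87.5 ± 33.1 to 1001 ± 547 (adjusted p = 0.0271). The orphan nuclear receptors Nr4a3 (ENSMUSG00000028341) and Nr4a1 (ENSMUSG00000023034) rose by 2.76 ± 0.56, from 4.79 ± 2.16 to 42.7 ± 22.5, and by 2.48 ± 0.50, from 12.2 ± 7.92 to 80.8 ± 59.1 (both adjusted p = 0.0237). Thbs1, a matrix glycoprotein, rose by 2.10 ± 0.43, Errfi1, an inhibitor of the EGF receptor, by 1.98 ± 0.38, and Apold1, an endothelial early response gene, by 1.97 ± 0.34. Gadd45g, a growth arrest gene, rose by 1.77 ± 0.35, the salt-inducible kinase Sik1 by 1.63 ± 0.30 and the insulin receptor substrate Irs2 by 1.53 ± 0.28. For each of these 9 genes all 6 exercised libraries lay above the sedentary mean.

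In all, 104 genes passed at ZT15, 78 higher and 26 lower, with 34 of the higher genes and 0 of the lower at 2-fold or more. The lower genes changed little: Zfp606, a zinc finger gene, fell by 0.55 on the log2 scale (SE 0.10, from 23.5 ± 2.21 to 15.8 ± 2.00), and Kbtbd7, Zfp65 and Zfp120 fell by 0.47, 0.41 and 0.40. With lymphocyte and muscle scores as covariates Zfp65 and Zfp120 missed the threshold (adjusted p = 0.0642 and 0.0746), and Zfp120 also with blocks of title numbers in the model (0.0515). The counts by edgeR and DESeq2 on recovered reads were 121 and 561. The split of 75% higher to 25% lower moved to 93.1% higher with quantile normalization, 89.7% with median centring and 58.6% with DESeq2.

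Of the 22 immediate early genes on the list, 22 had a change above 0 at ZT15, 4 passed over all genes and 11 passed adjusted over the list alone, with a median change of 0.85. Besides Nr4a1 and Nr4a3 these were Fosl2, a subunit of the AP-1 transcription factor (1.45 ± 0.27), and Dusp1, a MAP kinase phosphatase (1.31 ± 0.24); Fos itself differed by 1.15 ± 0.51 (adjusted p = 0.344). The list passed as a whole (camera adjusted p = 1.193e-14), with adjusted p = 0.339 with an estimated correlation. Of the 18 glucocorticoid-responsive genes 18 were above 0, 2 passed (Errfi1 and Dusp1) and 12 passed adjusted over the list alone, with a median of 0.80 (camera adjusted p = 4.474e-13; adjusted p = 0.339 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, differed by 1.34 ± 0.34, from 386 ± 100.1 to 1091 ± 658, and missed the threshold (adjusted p = 0.0613), as did the clock gene Per1 (0.83 ± 0.29, adjusted p = 0.192).

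Most genes of lipid use differed little one by one. Pdk4, given above, is also on the fatty acid oxidation list (386 ± 100.1 in ZT15 SED and 1091 ± 658 in ZT15 RUN). Of 22 fatty acid oxidation genes 21 were above 0, with a median of 0.23, 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 2.881e-03; adjusted p = 0.812 with an estimated correlation). Of 20 lipolysis genes 17 were above 0 (median 0.20, 0 passed, 1 adjusted over the list alone, camera adjusted p = 9.023e-03; adjusted p = 0.812 with an estimated correlation), among them the lipases Pnpla2 (0.20 ± 0.20) and Lipe (0.19 ± 0.17). Of the 38 respiratory chain genes 38 were above 0 (median 0.12, 0 passed and 0 adjusted over the list alone, camera adjusted p = 0.0223; adjusted p = 0.909 with an estimated correlation). Skeletal muscle markers moved with these lists, with 16 of 16 above 0 and a median of 0.80, and lymphocyte markers went the other way, with 20 of 20 below 0 and a median of -1.56. Respiratory chain scores among the exercised libraries at ZT15 were highest in ZT15_RUN_1 (2.14) and ZT15_RUN_6 (2.38), which were also highest in the muscle gene Myh4 (8995 and 22113). Both were highest in Ucp1 as well (532 and 526, against at most 17.7 in the other exercised libraries at ZT15). ZT15_SED_1 was likewise high in Myh4 (18297), Ucp1 (208) and this score (1.48). ZT3_SED_1 and ZT3_SED_4 were high in Myh4 (8207 and 6967) but not in Ucp1 (8.01 and 1.89) or this score (-0.56 and -0.45). The source of the high scores was not tested. With lymphocyte and muscle scores as covariates the lipolysis, oxidation and respiratory chain lists had adjusted p of 0.829, 0.286 and 0.929. Without the libraries high in Cd79a their camera adjusted p were 0.0546, 0.0350 and 0.373. Thermogenic genes did not pass as a list (median 0.21, adjusted p = 0.301), and Ucp1, the uncoupling protein of thermogenic fat, differed by 0.49 ± 1.35, at 184 ± 268 against 62.9 ± 76.5. The mean of 184 rested on ZT15_RUN_1 and ZT15_RUN_6. Ppargc1a, a coactivator of mitochondrial genes, differed by 1.37 ± 0.49 (adjusted p = 0.212), and Adipoq and Lep, adipocyte hormones, by 0.14 ± 0.22 and -0.30 ± 0.40.

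The ZT15 count was 22 without the 3 libraries high in Cd79a. Without these Irf4, Nr4a3, Thbs1, Errfi1, Fosl2 and Kbtbd7 had an adjusted p of 0.0605, Gadd45g and Irs2 of 0.0518, Nr4a1 of 0.0836, Zfp120 of 0.0996 and Zfp65 of 0.112, so their calls were lost, with log2 changes of 3.56 for Irf4 and 2.41 for Nr4a1. Without a single library the count was 293 (ZT3_RUN_4), 271 (ZT15_RUN_3) or 169 (ZT3_SED_1), and from 16 (ZT15_RUN_4) to 66 (ZT15_SED_4) without any one of ZT15_SED_1 to 6 or ZT15_RUN_1, 4, 5 or 6. Of the named genes Apold1 and Dusp1 passed without any single library. The others did not, with adjusted p of up to 0.0906 for Irf4, 0.0741 for Nr4a3, 0.0612 for Nr4a1, 0.0857 for Thbs1, 0.0718 for Gadd45g, 0.0534 for Sik1, 0.0511 for Fosl2 and Kbtbd7, 0.0989 for Zfp65 and 0.147 for Zfp120 (each without ZT15_RUN_5). It reached 0.0553 for Errfi1 and Zfp606 and 0.0515 for Irs2 (each without ZT15_RUN_4).

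**Figure D2:**
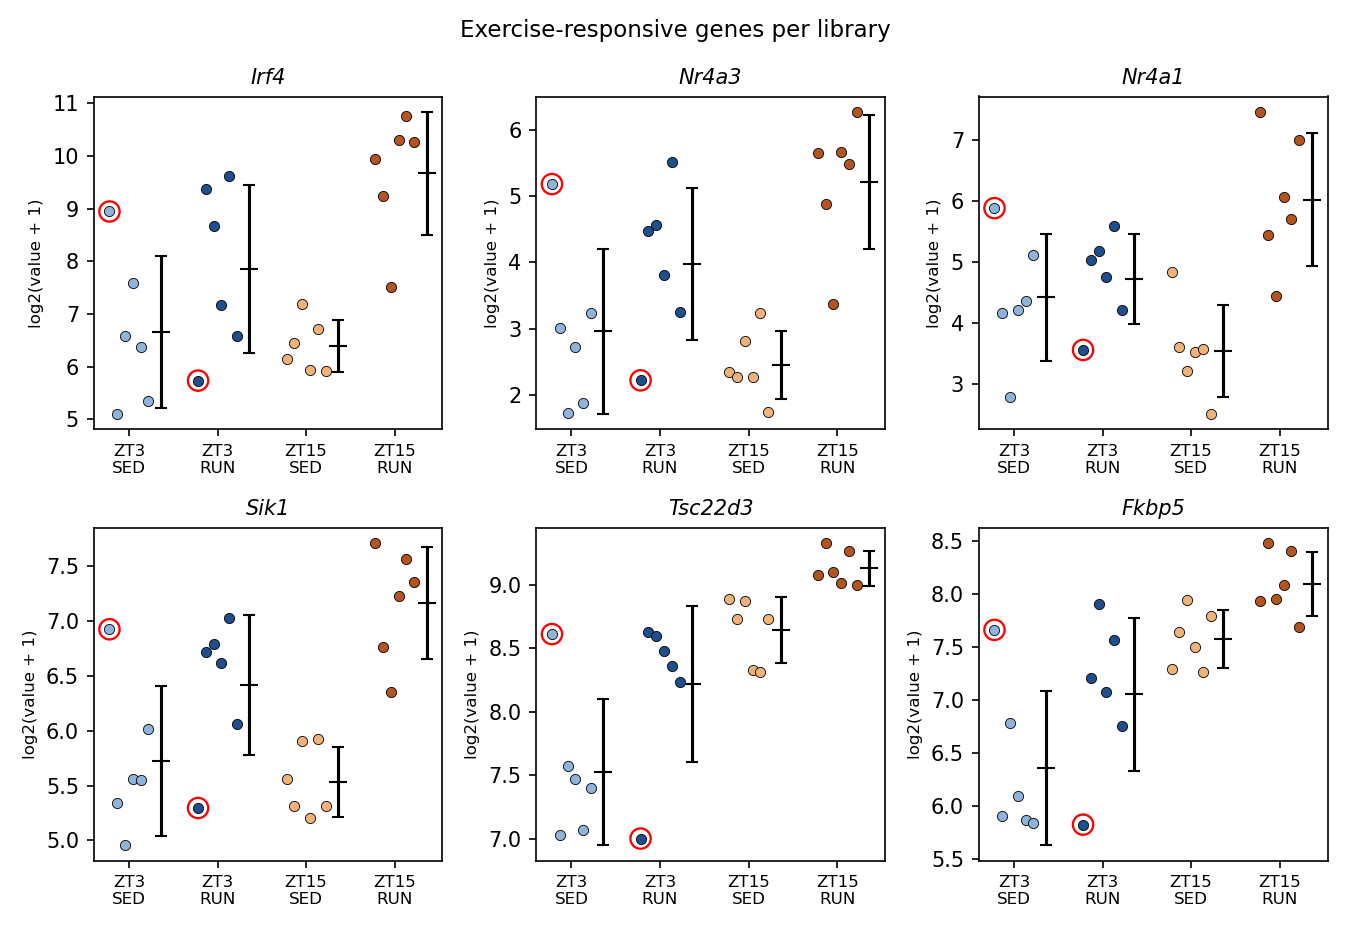
log2(value + 1) of 6 genes per library in the 4 groups, with mean ± SD (bars, n = 6); red circles mark ZT3_SED_1 and ZT3_RUN_1. Irf4 had means of 87.5 and 1001 in ZT15 SED and RUN, and Tsc22d3 was at 390 in the circled sedentary library and at 127 in the circled exercised one.

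The same comparison at ZT3, in the rest phase, gave no gene past the threshold with limma as labelled, 368 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.989. The counts by edgeR and DESeq2 were 0 and 0. The 5 genes of smallest p were Ppid, a cyclophilin (0.25 ± 0.07), the iron exporter Slc40a1 (-0.67 ± 0.19), the transcription factor Klf10 (-0.57 ± 0.18), Ifi35 (0.29 ± 0.09) and Ddit4, an inhibitor of mTORC1 signalling (1.39 ± 0.43, from 28.9 ± 22.2 to 72.6 ± 32.2). Genes of the ZT15 response varied widely within the ZT3 groups: Irf4 was at 357 ± 312 in RUN and 156 ± 174 in SED. Nr4a3 differed by 1.01 ± 0.56 and Nr4a1 by 0.30 ± 0.50. Of the 78 genes higher at ZT15, 67 were also above 0 at ZT3, with a median of 0.16 against 0.90.

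Among the lists, glucocorticoid-responsive genes had the smallest camera p at ZT3: 17 of 18 were above 0 (median 0.44), 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 3.379e-06; adjusted p = 0.812 with an estimated correlation). Fkbp5, a cochaperone of steroid receptors, differed by 0.70 ± 0.30, from 91.8 ± 57.4 to 145 ± 63.5, and Per1 by 0.50 ± 0.29. Immediate early genes did not move together (11 of 22 above 0, median -0.10, adjusted p = 0.104), and Fos was at 40.7 ± 34.2 in RUN and 72.4 ± 55.2 in SED. Extracellular matrix genes were lower as a list (3 of 21 above 0, median -0.19, camera adjusted p = 1.902e-04; adjusted p = 0.812 with an estimated correlation), as were lipolysis genes (2 of 20 above 0, median -0.15, camera adjusted p = 2.158e-03; adjusted p = 0.812 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Without the libraries high in Cd79a these last lists had adjusted p of 0.0717 and 0.880. With all libraries in, 20 of 20 lymphocyte markers were above 0 at ZT3 (median 0.83). Without the libraries high in Cd79a the direction of the lymphocyte list was down (camera adjusted p = 0.0527). Schwann cell and nerve markers were above 0 in 9 of 9 genes at ZT3 (median 0.31, camera adjusted p = 7.263e-03; adjusted p = 0.812 with an estimated correlation) and in 9 of 9 at ZT15 (median 0.55, camera adjusted p = 1.826e-04; adjusted p = 0.812 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. With covariates these had adjusted p of 1.029e-05 and 0.0316, and without the libraries high in Cd79a of 2.154e-06 and 0.0122.

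In several of these genes 1 library of each ZT3 group lay with the other group. Tsc22d3, a glucocorticoid-induced leucine zipper gene, was at 390 in ZT3_SED_1 against at most 189 in the other sedentary libraries, and at 127 in ZT3_RUN_1 against at least 299.8 in the other exercised libraries. Both libraries are kept under their labels in every result here. None of the alternative tests, scalings and models, and none of the fits without a single library, gave a gene at ZT3. Fits without 2 ZT3 libraries at a time, this pair among them, are described in the closing section only as a test of exchanged labels.

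The next question was whether the response to exercise differed between the times, tested as the interaction. No gene passed with limma (1273 genes at an unadjusted p under 0.05, smallest adjusted p 0.583), edgeR gave 0 and DESeq2 gave 239. Of these 239 the signed difference, ZT15 minus ZT3, was above 0 in 28 and below 0 in 211. A difference below 0 can be a smaller rise or a larger fall at ZT15. It can also reflect lymph node tissue, since the libraries high in Cd79a lie in ZT3 RUN and ZT15 SED. Lymphocyte markers were down as a list in this contrast (camera adjusted p = 1.032e-08, and 0.557 without those libraries). How many of the 211 genes follow lymph node tissue was not tested. The smallest p among named, expressed genes were those of Lrrc32, which anchors latent TGF-beta (1.15 ± 0.26), the actin-associated Palld (0.83 ± 0.21), the calcium pump Atp2a2 (0.38 ± 0.10), Tiparp (0.82 ± 0.22) and Fzd5, a Wnt receptor (1.05 ± 0.28). Of the 104 genes that passed at ZT15, 94 had an unadjusted interaction p under 0.05, but they were chosen on the ZT15 change that enters it. With limma over all genes, an effect at ZT15 alone is therefore not shown for any single gene.

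Immediate early genes differed as a list: 22 of 22 had a larger change at ZT15 (median difference 1.08), 0 passed over all genes and 11 adjusted over the list alone (camera adjusted p = 8.198e-14; adjusted p = 0.339 with an estimated correlation; fry 0.0740 and, for changes in either direction, 0.0156). Nr4a1 differed by 2.18 ± 0.71 and Fos by 1.95 ± 0.72 between the times. For lipolysis genes 19 of 20 were above 0 (median 0.35, 0 passed and 0 adjusted over the list alone, camera adjusted p = 1.250e-04; adjusted p = 0.812 with an estimated correlation). Extracellular matrix genes had a median of 0.39, with 20 of 21 above 0, 0 past the threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 4.365e-06; adjusted p = 0.812 with an estimated correlation). In the same contrast skeletal muscle markers had a median of 1.16, with 16 of 16 above 0, and lymphocyte markers of -2.37. With lymphocyte and muscle scores as covariates the adjusted p were 1.634e-18 for immediate early, 0.356 for lipolysis and 0.0752 for matrix genes.

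**Figure D3:**
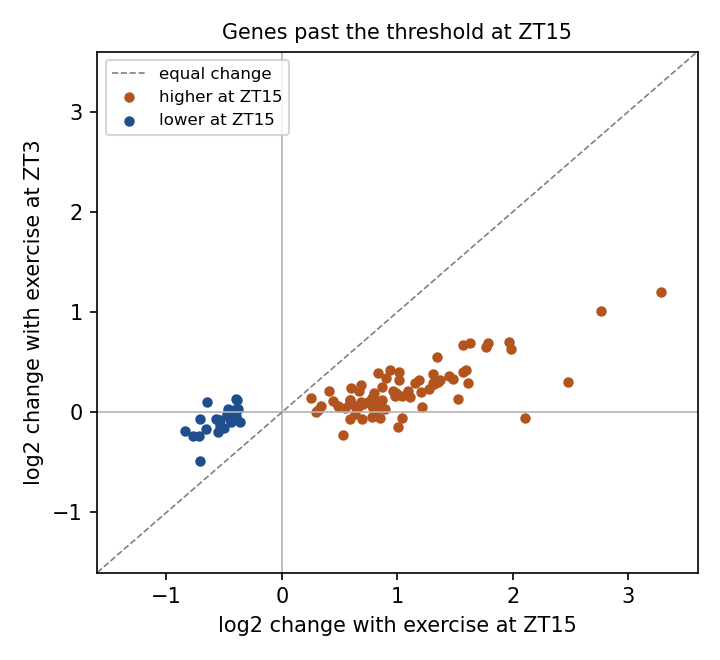
Log2 change with exercise at ZT3 (vertical axis) against ZT15 (horizontal axis) for the 104 genes past the threshold at ZT15; the dashed line marks equal change. Of the 78 higher genes 67 lie above 0 at ZT3, and their median change is 0.90 at ZT15 and 0.16 at ZT3; genes were chosen at ZT15, which enlarges that value.

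Averaged over both times, 23 genes passed, 20 higher and 3 lower, with 6 of the higher genes at 2-fold or more. The counts by edgeR and DESeq2 were 27 and 193. The count was 1 without the libraries high in Cd79a. Without a single library it was 165 (ZT3_SED_1), 114 (ZT3_RUN_1), 104 (ZT15_RUN_3), 71 (ZT3_RUN_4), 10 (ZT15_SED_5), 9 (ZT3_RUN_6), 1 (ZT15_SED_6) and 0 without any one of ZT3_SED_2 to 6, ZT3_RUN_2, 3 or 5, ZT15_SED_1 to 4 or ZT15_RUN_1, 2, 4 or 5.

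The last comparison asked which genes differed between ZT15 and ZT3 in sedentary mice. Clock genes led it: Nr1d1 (ENSMUSG00000020889), which encodes the repressor REV-ERB alpha, was lower at ZT15 by -3.05 ± 0.19, at 9.27 ± 2.20 against 83.1 ± 10.5 (adjusted p = 7.971e-10). Cry1 (1.58 ± 0.12, adjusted p = 7.166e-08) and Per2 (1.99 ± 0.26, adjusted p = 2.403e-04), which encode repressors of the clock, were higher at ZT15, as was Hlf (1.47 ± 0.24), while Npas2, which encodes a partner of BMAL1, was lower (-1.37 ± 0.23). Arntl, which encodes BMAL1, was at 22.0 ± 7.46 and 22.7 ± 3.73, and Dbp differed by -0.33 ± 0.22 (adjusted p = 0.605). Of the 12 genes of the Per and Rev-erb arm 2 passed as higher and 1 as lower (4 and 1 adjusted over the list alone).

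In all, 191 genes passed, 100 higher and 91 lower at ZT15. Metabolic genes among the largest changes were Slc2a3, a glucose transporter (1.30 ± 0.24), the monooxygenase Fmo2 (1.27 ± 0.20), Trp53inp2, an autophagy gene (1.25 ± 0.17), and, lower, Pfkfb3, which makes an activator of glycolysis (-1.17 ± 0.18), and the phosphodiesterase Pde3a (-1.02 ± 0.14). The glucocorticoid-responsive Fkbp5 (1.21 ± 0.30) and Tsc22d3 (1.12 ± 0.25) were higher at ZT15; as a list these genes did not pass (median 0.16, adjusted p = 0.183). The cell cycle kinase Wee1 was higher (1.19 ± 0.25), and Ccn1 and Igsf10 were lower (-1.54 ± 0.36 and -1.08 ± 0.19). Lep, the hormone leptin, was at 673 ± 259 at ZT15 and 333 ± 142 at ZT3 and did not pass (adjusted p = 0.249). The beta-3 adrenergic receptor Adrb3 did not pass either (-0.60 ± 0.22, adjusted p = 0.236).

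Extracellular matrix genes were lower at ZT15 as a list, with 20 of 21 below 0 (median -0.61), 3 past the threshold and 13 adjusted over the list alone (camera adjusted p = 1.194e-13; adjusted p = 0.339 with an estimated correlation). The 3 were Fbn1, which encodes fibrillin (-1.56 ± 0.38), the membrane metalloprotease Mmp14 (-0.92 ± 0.19) and Col1a1, a chain of type I collagen (-0.93 ± 0.23), and Loxl2, a collagen crosslinking enzyme outside the list, was lower as well (-1.10 ± 0.23). Immediate early genes were lower (21 of 22 below 0, median -0.71, 1 passed and 9 adjusted over the list alone, camera adjusted p = 1.114e-08; adjusted p = 0.686 with an estimated correlation), led by Fos at 10.8 ± 5.78 against 72.4 ± 55.2. Macrophage markers were lower (10 of 12 below 0, median -0.51, 0 passed and 3 adjusted over the list alone, camera adjusted p = 6.585e-04; adjusted p = 0.812 with an estimated correlation). Heat shock chaperones were higher (18 of 19 above 0, median 0.31, 1 passed, Hspa8, and 5 adjusted over the list alone, camera adjusted p = 6.552e-07; adjusted p = 0.812 with an estimated correlation). Preadipocyte and fibroblast markers, of cells that make matrix, were lower with the matrix genes (9 of 10 below 0, median -0.42, 0 passed and 0 adjusted over the list alone, camera adjusted p = 0.0322; adjusted p = 0.812 with an estimated correlation). Without the libraries high in Cd79a their adjusted p was 0.370, with covariates 0.581 and with blocks of title numbers 4.469e-03. Skeletal muscle markers had a median of -1.57 and lymphocyte markers of 1.46 in this contrast, and with both scores as covariates the matrix list had an adjusted p of 1.595e-06 and the macrophage list of 0.136. Of the named matrix genes Mmp14 passed with these covariates and with edgeR (adjusted p = 0.0195 and 0.0141), while Fbn1 (0.0585 and 0.0501) and Col1a1 (0.0605 and 0.0564) did not.

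The time-of-day count was 192 with edgeR, 548 with DESeq2, 287 with the blocks of title numbers in the model and 388 without ZT3_RUN_4. The other single libraries left it within 1.5 times. Nr1d1, Cry1 and Per2 passed without any single library. Col1a1, Fbn1, Hspa8, Fkbp5, Ccn1 and Tsc22d3 lost the threshold in some of these fits, with adjusted p of up to 0.119, 0.111, 0.124, 0.117, 0.0856 and 0.0613 (without ZT3_SED_2, ZT3_SED_4, ZT3_SED_4, ZT3_SED_4, ZT3_SED_6 and ZT3_SED_2). Without the libraries high in Cd79a Fkbp5 (adjusted p = 0.0998), Ccn1 (0.0817) and Fbn1 (0.0644) missed it as well, and Fkbp5 also missed it with edgeR (0.0995).

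**Figure D4:**
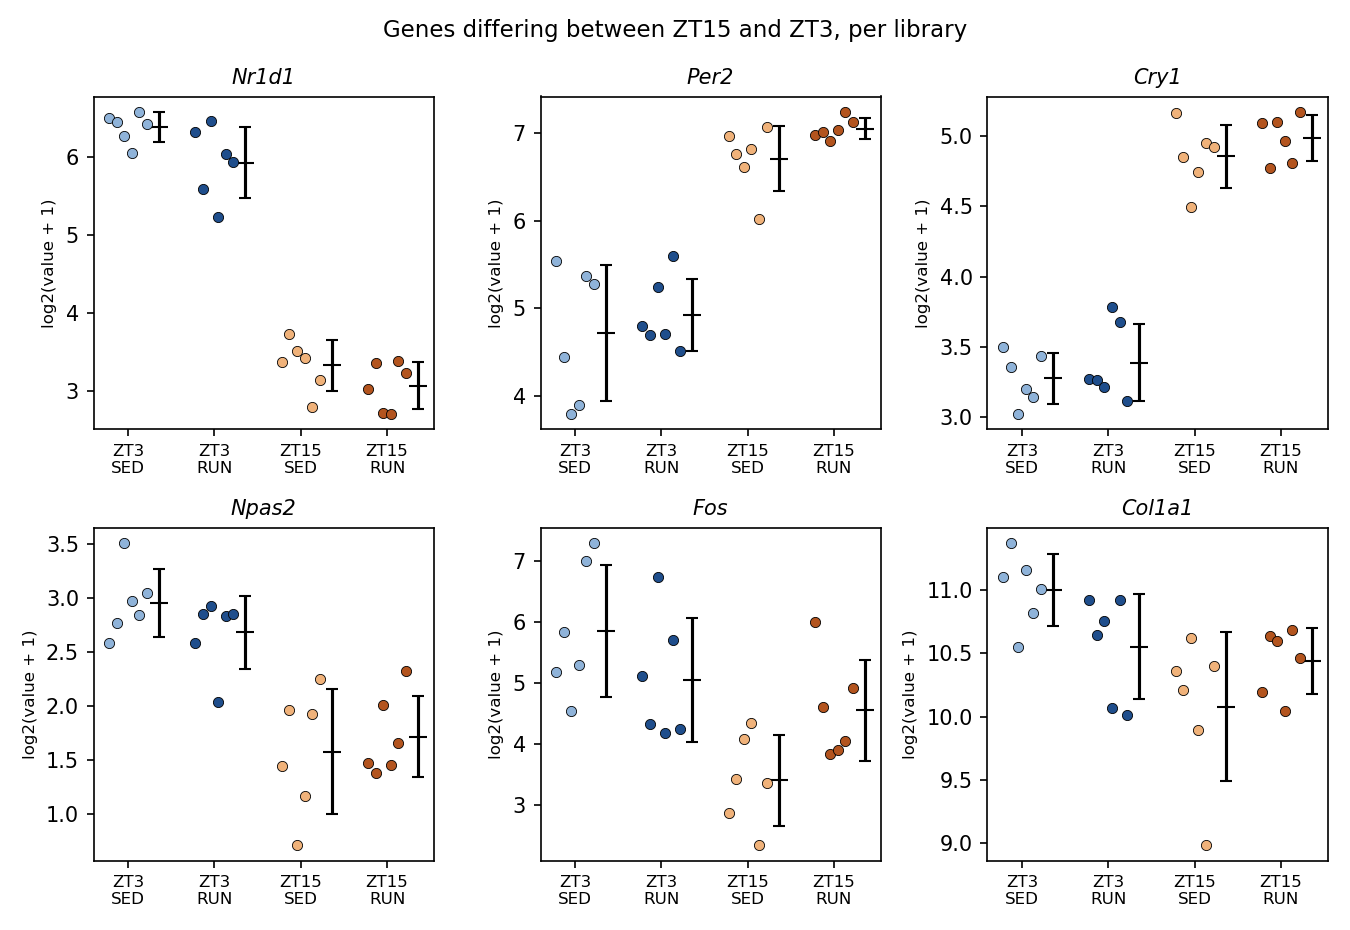
log2(value + 1) of 6 genes per library in the 4 groups, with mean ± SD (bars, n = 6). Nr1d1 reached at most 12.3 in ZT15 SED and lay at 65.7 or more in ZT3 SED.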

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

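The splits of the samples at ZT3 and for the interaction, the splits within blocks of title numbers, the test of the sham level, both tests of exchanged labels, and the choice of zinc finger genes as a group with the test of their median over all splits were made after the results were seen.

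Other splits of the same libraries tell how often chance alone gives as many genes. At ZT15, 1 of 100 splits, the real one, gave 104 genes or more (highest other 0). For time of day in sedentary mice 1 of 100 gave 191 or more (highest other 3). Chance is thus argued against for both counts, although 100 splits can resolve no less than 1 in 100. For exercise averaged over both times 2 of 100 gave 23 or more, but the highest other split called 414. Between the blocks of 8 title numbers 523 genes differed beside the groups, and the libraries also differed in lymph node and muscle tissue. Whether any of these gave the 414 calls was not tested. At ZT3 the real count was 0, so 100 of 100 splits gave as many (highest other 5). For the interaction the real count was also 0, so 100 of 100 gave as many, and the highest other called 361, the source of which was not tested either. Among 100 splits that kept 2 libraries of each group in every block, with the blocks in the model, the highest other fell to 0 for the average (real 16) and to 3 for the interaction (real 0), while at ZT15 it was 3 (real 103) and for time of day 17 (real 287). At ZT3 it was 76 (real 0, next highest 2), in the split that exchanges ZT3_SED_1 and ZT3_RUN_1 alone. The splits within blocks were drawn anew, so their lower counts do not show that the blocks gave the 414 or the 361 calls.

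The first pattern is that genes passed at ZT15 and none at ZT3. Lymph node tissue is argued against as its source, since without the 3 libraries high in Cd79a the median change of the 104 genes was 0.72 against 0.78 with them. The 104 genes were chosen with the 3 libraries in, and fewer passed without them (22). Over the 90 trios drawn from the same groups the median count was 5.5 (from 0 to 571). Most of these trios keep ZT3_RUN_4, without which alone 293 passed, so this median cannot tell whether 22 is few. A change of equal size at ZT3 hidden by spread cannot be told apart from a smaller one: genes chosen in the other blocks had medians at ZT15 of 0.71, 0.63 and 0.58 in the held-out block and at ZT3 of -0.01, -0.21 and 0.40, and the last keeps it open, while the second of these blocks holds the ZT3 pair weighed next. Genes chosen at ZT3 had held-out medians of -0.11, -0.23 and 0.06 at ZT3 and of 0.01, 0.44 and 0.07 at ZT15. With the second block held out, they were chosen without that pair. An exchange of the labels of ZT3_SED_1 and ZT3_RUN_1 cannot be told apart either: of 100 genes chosen without both, 94% placed ZT3_SED_1 nearer the exercised mean and 95% placed ZT3_RUN_1 nearer the sedentary mean (highest for another sedentary library 69% and for another exercised library 86%), but 5 of 36 pairs were crossed in this way, and 2 mice responding against their groups would give the same values. Over the 36 pairs, 19 genes passed at ZT3 without this pair and 65 with its labels exchanged, against at most 1 for any other pair; the pair was picked from its values, so these counts only describe it, and the labels were kept.

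The second pattern is that immediate early genes had a larger change at ZT15 than at ZT3. Lymph node and muscle tissue are argued against as its source, since with both scores as covariates the median difference was 1.02 against 1.08; other cell types were not adjusted for. An exchange of the ZT3 pair is argued against as its whole source, since without both libraries the median was 0.94. The median with their labels exchanged was not computed, so a part of the difference from an exchange stays open. A higher level in sham mice at ZT3 cannot be told apart from a larger response at ZT15, because the sham difference is itself a term of the interaction and was known beforehand: the sham score was 0.19 ± 0.69 at ZT3 and -0.71 ± 0.15 at ZT15 (exact permutation p = 0.0108), and the exercised score was -0.02 ± 0.56 at ZT3 and 0.55 ± 0.59 at ZT15. Why the sham level differed was not tested, and time of day stays open.

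The third pattern is that zinc finger genes made up 11 of the 26 genes lower at ZT15, of 361 Zfp genes in the table, and 3 of the 78 higher. The group was noticed among these genes. Over all 924 splits of the ZT15 libraries the median of all Zfp genes, -0.17, had an exact permutation p of 2.165e-03. The splits did not repeat the choice of the group, so this p is no support for a fall of the Zfp genes. Their expression level is argued against as the source, since 0% of 10000 lists matched on expression had a median as low (from -0.07 to 0.03), which describes these libraries only, as genes that vary together are not independent. Scaling cannot be told apart from a lower level: after quantile normalization their median relative to all genes was -0.13, between the bounds set for either reading, and only 5 lower genes passed. The Zfp median relative to all genes was -0.17 in the main fit. It was -0.14 with lymphocyte and muscle scores as covariates and -0.16 without the libraries high in Cd79a. No bounds were set beforehand for these values, so tissue content was not weighed as a source. No biological cause was tested.

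Libraries far from the rest of their group were looked for in 300 sets of 6 values. About 15 would be met by chance if values were normally distributed and sets independent. Gene values were not on a log scale and the sets share genes, so 15 is no firm yardstick for the 35 found. In ZT3_SED_1 they were Per1 (163), Fkbp5 (202), Irf4 (492), Apold1 (44.9), Sik1 (120), Fosl2 (202), Nr4a3 (35.2) and Tsc22d3 (390), all high, and in ZT3_RUN_1 Tsc22d3 (127), low. In ZT3_RUN_4, the library highest in Cd79a, they were the scores of lymphocyte markers (3.00), lipolysis (-2.16), extracellular matrix (-1.16) and adipocyte markers (-2.79), Lipe (660) and the scale factor (1.19). In ZT15_SED_5, also high in Cd79a, they were the extracellular matrix score (-2.25), Wee1 (16.7) and Loxl2 (14.5). In ZT15_SED_1 they were the scores of the respiratory chain (1.48) and of hypoxia and glycolysis (0.65), Nr4a1 (27.6), Ucp1 (208) and Ppargc1a (42.5). In ZT15_RUN_1 they were Fos (62.8), Dusp1 (166) and Ccn1 (117), in ZT3_RUN_5 Pdk4 (715), Ppargc1a (54.1) and Thbs1 (190), and in ZT15_RUN_3 Dbp (8.48) and Zfp65 (14.8). Single values were the lipogenesis score of ZT3_SED_4 (-1.20), the neutrophil score (0.80) and the depth (18.5 M reads) of ZT15_RUN_5, and the keratinocyte score of ZT3_RUN_3 (1.48).

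The interaction passed for 10 lists, by camera adjusted p: the Per and Rev-erb clock arm (0.0127), immediate early genes (8.198e-14), glucocorticoid-responsive genes (0.00142), lipolysis (1.250e-04), fatty acid oxidation (5.949e-04), the respiratory chain (0.0116), extracellular matrix (4.365e-06), adipocyte markers (0.0388), endothelial markers (0.0129) and lymphocyte markers (1.032e-08). Without the libraries high in Cd79a and with covariates the calls were lost for the clock arm (0.182 and 0.215), fatty acid oxidation (0.0717 and 0.225), the respiratory chain (0.898 and 0.597), adipocyte markers (0.846 and 0.245, and 0.0504 with blocks of title numbers), endothelial markers (0.325 and 0.529) and lymphocyte markers (0.557 and 0.882). With covariates alone they were lost for glucocorticoid-responsive genes (0.0562), lipolysis (0.356) and extracellular matrix (0.0752), and immediate early genes passed in both. With an estimated correlation none of them passed, with adjusted p from 0.339 for immediate early genes to 0.909.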

How the results depend on the processing

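Results are compared here as counts of genes past an adjusted p of 0.05 unless another threshold is named. Chosen after the results were seen were edgeR, DESeq2, the fits without the 3 libraries high in Cd79a, the covariates joined with title-number blocks, and the list tests with covariates or blocks. Exercise at ZT15 (104 genes): 270 with sample weights, 300 at an adjusted p under 0.1, 34 at a log2 fold of at least 1, 561 with DESeq2 (101 shared) and 22 without the libraries high in Cd79a (21 shared). Interaction (0): 239 with DESeq2. ZT15 against ZT3 in sedentary mice (191): 287 with title-number blocks, 713 with weights, 548 with lymphocyte and muscle scores as covariates, 387 at 0.1, 39 at a fold of 1, 548 with DESeq2 and 742 with covariates and blocks. Exercise averaged over both times (23): 8 with quantile normalization, 15 without the lowest 25% of expression, 187 with weights, 132 with covariates, 94 at 0.1, 6 at a fold of 1, 193 with DESeq2, 1 without the libraries high in Cd79a and 104 with covariates and blocks. Exercise at ZT3 gave 0 genes in each of these settings; fits without ZT3_SED_1 and ZT3_RUN_1, picked from their values, gave 19 and are weighed with the patterns above. Without any one library the ranges were 0 to 0 at ZT3, 16 to 293 at ZT15, 0 to 0 for the interaction, 130 to 388 for time of day and 0 to 165 for the average. Of 100 list tests 38 passed, against 0 with an estimated correlation, 1 with fry, 22 without the libraries high in Cd79a (17 shared) and 18 with covariates (13 shared). Some lists changed direction: lymphocyte markers at ZT3 (adjusted p 0.0527 without the libraries high in Cd79a, 0.726 with covariates), the respiratory chain at ZT15 (0.929 with covariates) and in the interaction (0.898 and 0.597), and adipocyte markers in the interaction (0.846 and 0.245). Of 37 named calls 0 changed direction, and 37 passed with DESeq2, 34 with edgeR, 33 with covariates, 33 with quantile normalization, 36 with blocks, 30 with only the 2 groups compared, 23 without the libraries high in Cd79a and 18 without any single library. The cause of these moves was not tested, except for the libraries high in Cd79a. The labels pair no libraries. With neighbouring title numbers (1 and 2, 3 and 4, each 1 exercised and 1 sedentary library) as a replicate block, an added fit, 19 genes passed at ZT15 (17 shared), 0 at ZT3, 0 for the interaction and 0 for the average, and of the named exercise calls 5 passed and 10 were lost. Only 7 of these 12 pairs had deviations correlated over 0.1 (from -0.44 to 0.78), and 3 pairs fitted best with each other, so the numbers are not taken as pairs.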

Other observations

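Heat shock chaperones were above 0 after exercise at both times, in 17 of 19 genes at ZT15 (median 0.16, camera adjusted p = 1.128e-03; adjusted p = 0.812 with an estimated correlation) and in 17 of 19 at ZT3 (median 0.15, camera adjusted p = 2.956e-03; adjusted p = 0.812 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Without the libraries high in Cd79a the ZT15 call was lost (camera adjusted p = 0.267) and the ZT3 call kept (1.989e-03). With lymphocyte and muscle scores as covariates both calls were kept (camera adjusted p = 0.0481 at ZT15 and 3.330e-06 at ZT3). With all libraries in, lymphocyte markers had medians of -1.56 at ZT15 and 0.83 at ZT3. Endothelial markers were above 0 in 12 of 12 at ZT15 (median 0.19, 0 passed and 1 adjusted over the list alone, camera adjusted p = 8.153e-03; adjusted p = 0.812 with an estimated correlation). This call was lost without the libraries high in Cd79a (adjusted p = 0.0572) and with lymphocyte and muscle scores as covariates (0.282).

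Glucocorticoid-responsive genes were above 0 at both times, in 18 of 18 genes at ZT15 and 17 of 18 at ZT3. At ZT3 no member passed, and with an estimated correlation the list passed at neither time. Stress hormones rise with exercise, but whether they moved these genes was not tested. A test that the series would allow, if the authors hold such records, is whether blood corticosterone of the same mice follows Tsc22d3 and Fkbp5.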
